A study of Mus musculus with 2 samples.

How the data were processed

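H3K4me1 was measured by ChIP-seq in 2 biological replicates of heart from newborn mice, replicate 1 from 15 pooled mice and replicate 2 from a pool of unstated size, both of mixed sex. Per the labels these are separate biological replicates of 1 group, and there was no second group, so no test between groups was made. The spread between the replicates is given as a mean ± SD with n = 2. The control libraries, alignments and read counts were not used here, so the depth per sample is unknown and the precision that it gives cannot be stated.

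The 4 peak lists were deposited by the authors without header lines, in narrowPeak format on mm10. Per the file descriptions deposited with them, each replicate list was called on 1 replicate against 1 control file, the pooled list on both replicates with 2 control files, and the replicated list was derived from those 3 lists. The name of the peak caller, the aligner and the rule for the replicated list are not given in the sources used here. The signal value of each peak (column 7) is the authors' deposited value and its scale is not stated, so it was used only to rank or describe peaks. The −log10 p (column 8) and −log10 q (column 9) are the authors' deposited values, and the lowest −log10 p in each list was about 2. Because weak peaks were kept by the authors, replicate lists were filtered here at q of 0.05 or lower, a −log10 q of at least 1.30. All deposited replicate peaks were used only where they were compared with the pooled or replicated list, to find peaks that met none in the other replicate, and where stated. The pooled and replicated lists were used as deposited. Pooled and replicated lists rest on both replicates and so have no SD.

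Peaks on chromosomes 1 to 19 and X were used, and 2 peaks of replicate 2 on unplaced sequence were left out. Genes, exons and start sites came from GENCODE M21 and the sequence from GRCm38, the assembly that mm10 names, and all peak ends lay within its chromosome lengths. Protein-coding genes were counted once per symbol (21728). A gene's territory was its body plus 10 kb on each side, territories of neighbours can overlap, and coverage is the percent of the territory inside peaks. For each of 20 lists of genes fixed before the data were examined, with 279 genes that were all found, the median coverage was placed among 10000 random lists of the same size matched on 10 classes of territory length. A list stood apart at or above the 97.5th or at or below the 2.5th percentile. These percentiles describe the libraries and are not p-values. With 20 lists about 1 would pass by chance. The same was done for the difference between replicates.

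Overlap required 50% of a peak's length to be covered (1 bp for pairs whose signal was correlated and for peaks said to meet or not to meet another), and 20 random placements of the peaks within chromosomes gave the background. Peak centres were assigned to a start site within 1 kb, then to an exon, an intron or intergenic sequence. Domains joined peaks less than 12.5 kb apart. Each of 20 consensus sequences was counted on both strands in windows of 1 kb, and its peak-to-control ratio was placed among up to 50 letter permutations of the consensus.

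The measures were tested on simulated data. Of 200 random lists on shuffled peaks 3.5% were called apart. They were drawn from the same genes as the lists they were ranked among. A low share was therefore built in, and it gives no rate of false calls for the fixed lists. Of 50 lists of 16 genes with their coverage multiplied by 1.5, 2, 3 and 4, respectively 20%, 50%, 60% and 78% were called. The last share missed a bound of 80% set in advance for this test. The bound was then dropped and the share kept as measured, since genes without a peak, 29.0% of all, stay at 0 when multiplied. In a simulation added after that result, with 2, 5 and 10 percentage points added, 22%, 78% and 100% were called. A list that did not stand apart can therefore still be covered several times better than other genes. An overlap simulated with 40% of the peaks kept in place came out as 41.3%, and the counts of all 20 consensuses equalled those of a text search.

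The genes named were chosen by a rule fixed in advance. It took 10 heart genes, the 2 highest and the lowest of each list, the 15 highest of all genes, those nearest to the 10 strongest replicated peaks, those in the 10 domains with the most covered sequence, and those nearest to the 5 strongest peaks of each replicate that met no peak of the other. Genes hosting a strong peak in an intron or exon are named beside it, and Klf13 is named as the host of another gene.

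Alternatives fixed in advance were other q thresholds, overlap rules, start site distances, territories and summaries, unmatched random lists, other windows and controls, a smaller joining gap, equal numbers of top peaks, and each replicate alone. Alternatives chosen after seeing the data were autosomal genes only, peaks over 2.5 kb from a start site, and permutations with the same number of CpG. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.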

Results

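Histone H3 monomethylated at lysine 4 (H3K4me1), a mark found at enhancers and beside promoters, was mapped by chromatin immunoprecipitation and sequencing in the hearts of newborn mice (age 0 days, both sexes pooled). There was 1 group with 2 biological replicates. Replicate 1 was a pool of 15 mice, and the number of mice pooled for replicate 2 was not stated. The files held 4 peak lists on mm10 and no read counts, so the sequencing depth is unknown and no interval that needs it is given. The question the design allowed was where the mark lay in newborn heart and how closely the replicates matched, since no second condition was included. The authors' list of replicated peaks held 93169 peaks with a median width of 569 bp, which covered 66.1 Mb, or 2.58% of the non-gap genome. At q of 0.05 or lower, replicate 1 had 125962 peaks and replicate 2 had 154473, and these covered 2.03% ± 0.413 of the genome (SD, n = 2). The sequence shared by these 2 sets of peaks was 21.6 Mb, of 82.4 Mb covered by either. Replicated peaks are peaks of the pooled list, with the ends called there. Their coverage is therefore not the sequence marked in both replicates, and it can exceed the coverage in either replicate.

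In 4 lists, genes of the heart muscle cell carried far more of the mark than other genes of similar length. The 22 sarcomere genes, which encode the contractile apparatus, had a median of 12.1% of their territory (gene body plus 10 kb on each side) inside replicated peaks. The 20 cardiac transcription factor genes had a median of 11.9%, and the 16 genes of calcium handling and conduction had 11.3%. The median of random lists matched on territory length was 2.79%, 2.72% and 2.63%, respectively, so the heart lists were 4.35, 4.36 and 4.29 times as high. The 18 genes of fatty acid oxidation and energy supply, the main fuel pathway of the mature heart, had 9.76%, against 2.98% in random lists. The first 3 of these lists lay at the 100th percentile of 10000 random lists and the fatty acid list at the 99.95th. In the separate replicates the medians were 9.14% ± 2.68 for the sarcomere, 8.25% ± 1.78 for the transcription factors, 8.67% ± 1.40 for calcium handling and 6.55% ± 1.12 for fatty acid oxidation (SD, n = 2), and all 4 lists lay above the central 95% of random lists in each replicate. No p-value is given, because genes are not replicates and there was no second group.

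**Figure D1:**
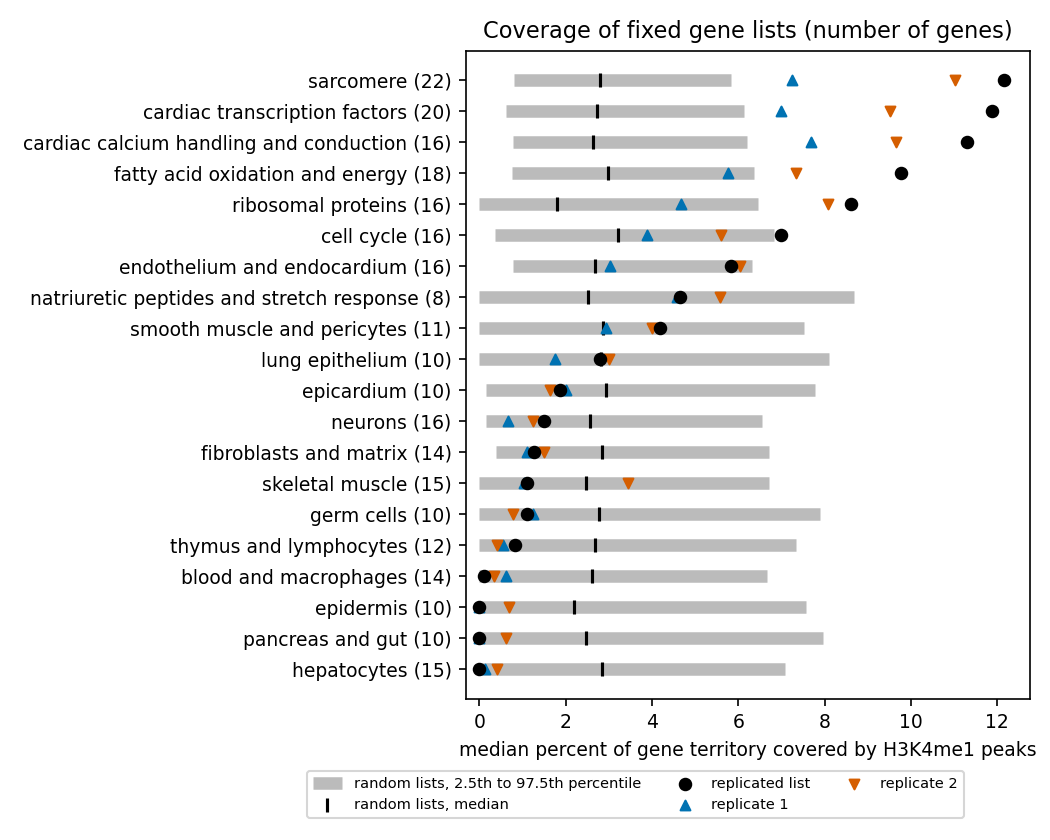
Median percent of gene territory covered by H3K4me1 peaks (x axis) for 20 gene lists fixed in advance (y axis, number of genes in parentheses), with black circles for the replicated list, triangles for the 2 replicates, and grey bars for the central 95% of random lists matched on length, with a tick at their median (bars and ticks are for the replicated list only; each replicate was ranked against its own random lists). The sarcomere list at 12.1%, the cardiac transcription factors at 11.9% and calcium handling at 11.3% lie to the right of their grey bars, while hepatocytes, epidermis and pancreas and gut lie at 0.

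Within the transcription factor list, 19 of 20 genes had a replicated peak in their territory and 9 were among the 10% of genes with the highest coverage. Gata4, a zinc finger regulator of heart development on chromosome 14 (63198922 to 63271692, minus strand), had 34 replicated peaks over 31.8% of its territory, and the replicates gave 19.3% ± 4.75 (SD, n = 2). Tead1, the effector of Hippo signalling, had 72 peaks over 30.1%. Tbx5 had 11.6%. Hand2 had 17.7%, with 12.6% in replicate 1 and 5.89% in replicate 2. Nkx2-5, on chromosome 17 (26838664 to 26845009), had 3 peaks over 6.54%. Isl1, a marker of early cardiac progenitors, had no replicated peak, and its coverage in the replicates was 0.322% ± 0.455 (SD, n = 2).

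**Figure D2:**
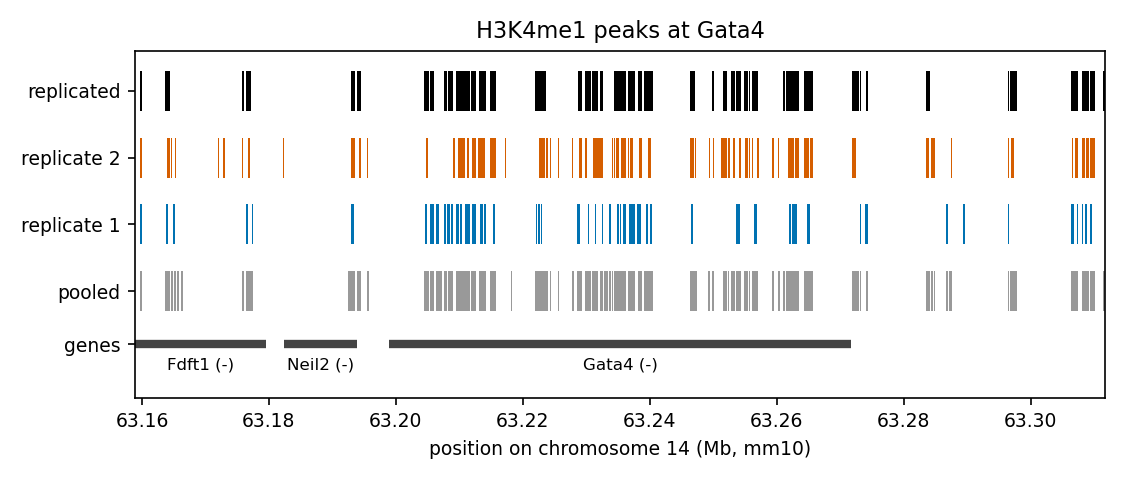
Peaks of the 4 lists (rows, with filled blocks for peaks) along chromosome 14 in Mb on mm10, over Gata4 and 40 kb on each side, with protein-coding genes as dark bars and their strand in parentheses. The replicated list has 45 peaks in the window, against 55 in replicate 1 and 67 in replicate 2 at q of 0.05 or lower and 73 in the pooled list.

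All 22 sarcomere genes had a replicated peak, and 18 lay above the median of all genes, which was 2.73%. Tcap, which encodes the titin cap protein, had 50.1% of its territory covered and ranked among the 15 highest of 21728 protein-coding genes. Tnni3, the cardiac troponin I gene, had 31.9%. Tnnt2, the cardiac troponin T gene, had 31.3%, but the replicates differed widely, with 9.18% in replicate 1 and 30.7% in replicate 2. Coverage was lower at other genes of the same class. Ttn had 0.999% and Myh6, the adult cardiac myosin heavy chain, had 1.42% (0.378% in replicate 1 and 2.80% in replicate 2). Actc1, cardiac actin, had 3.38%, above the median of all genes (0.944% and 4.80%). Myh7, the fetal cardiac myosin next to Myh6, had 12.3% (6.76% and 12.8%), and the territories of these neighbours overlap, so that a peak can count for both. Among calcium handling and conduction genes, Kcnh2, a potassium channel, had 33.1%, Jph2, a junctional membrane protein, had 31.0%, the calcium release channel Ryr2 had 76 peaks over 11.5%, and Trdn had 1.11%. Ppargc1a, a coactivator of mitochondrial genes, had 19.8% and Fabp3, a fatty acid binding protein of muscle, 18.5%, while Pdk4 had 2.52%. In the list of natriuretic peptide and stretch response genes the median was 4.64%, at the 78.6th percentile. Fhl2 had 33.6%, Rcan1 22.7%, Nppa 5.04% and Xirp2 0.883%. That list was at the 99.9th percentile with territories of 50 kb on each side and at the 98.3rd by the mean. The replicates differed by over 1.5 times in coverage at 48 of the 115 named genes, with replicate 2 higher at 41 of these. List medians could differ as much, as in the sarcomere list with 7.24% in replicate 1 and 11.03% in replicate 2. The median over all protein-coding genes was also higher in replicate 2, at 2.56% against 1.82% in replicate 1.

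Lists for other cell types of the heart did not stand apart at the main setting. The 16 endothelial and endocardial genes had a median of 5.83%, at the 96th percentile, with Notch1 at 18.2%, Eng at 16.3% and Tie1 without a replicated peak. This list was at the 98.6th percentile in replicate 2 and at the 87.1st in replicate 1. Smooth muscle and pericyte genes had a median of 4.19% (74.3rd percentile), with Des at 23.1% and Cspg4 at 18.6%, and Rgs5 had none. Epicardial genes had 1.87% (26.04th percentile), led by Krt19 at 7.26%. Fibroblast and matrix genes had 1.27% (percentile 11.99), led by Col1a1 at 9.84%, and Tcf21 had none. Blood and macrophage genes had 0.102% (3.32nd percentile), led by Cd68 at 9.88%. They had 0.630% in replicate 1 (percentile 11.5) and 0.350% in replicate 2 (percentile 2.79). With autosomal genes only, a setting chosen after seeing the data, they had 0.781% (percentile 9.98).

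Lists for other organs lay at or below the middle of the random lists in the replicated list at the main setting. Hepatocyte, pancreas and gut, and epidermis genes each had a median of 0, at percentiles of 3.005, 2.815 and 6.415. A median of 0 is the lowest possible, and random lists tied at 0 count in part. These were therefore the lowest percentiles that the 3 lists could reach, and the 2.5th could not be passed at the main setting. With the mean in place of the median all 3 passed it, at 1.09, 0.18 and 0.97. Lung epithelium genes stood at the 49.4th percentile, neurons at the 22.7th, germ cells at the 18.7th, thymus and lymphocytes at the 16.9th and skeletal muscle at the 16.8th. Skeletal muscle was at the 77.0th percentile in replicate 2 (median 3.45%) and at the 25.9th in replicate 1 (median 1.03%), and lung was at the 57.5th in replicate 2 and the 60.7th with territories of 50 kb. The highest members were Sftpc at 12.03% for lung, Neurod2 at 8.29% for neurons, Prm2 at 11.04% for germ cells, Lck at 6.90% for thymus, Mylpf at 14.0% and Myog at 14.0% for skeletal muscle, and Ttr at 8.36% for hepatocytes.

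Genes used by most cells were also included. The 16 ribosomal protein genes had a median of 8.62% against 1.80% in random lists, 4.80 times as high and so above the ratio of every heart list, at the 99.7th percentile, led by Rpl3 at 21.2%, and all 16 had a replicated peak. With peaks centred within 2.5 kb of a transcription start site left out, a setting chosen after seeing the data, the list fell to a median of 0. The median of its random lists was also 0 there, so its 49.5th percentile is a tie at 0 and not a mid-range rank. The 16 cell cycle genes had a median of 7.001%, at the 97.9th percentile, led by E2f1 at 16.7%. They fell inside the central 95% of random lists under 6 of the 8 alternatives fixed in advance. Without the peaks beside start sites they were at the 40.9th, also a tie, with a median of 0 in the list and over its random lists.

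Replicated peaks were concentrated near genes. A transcription start site (TSS) lay within 1 kb of 19.3% of peak centres, against 6.38% ± 0.0770 (SD over 20 shuffles of the peaks within chromosomes), a ratio of 3.02. Introns held 55.5% (1.37 times the shuffled share), exons 3.99% (1.16 times) and intergenic sequence 21.2% (0.427 times). The replicates gave 16.95% ± 0.222 near a TSS (SD, n = 2). With 2.5 kb as the limit the share was 32.2%. The mark was lower at the TSS than in its immediate flanks. Replicated peaks covered the TSS of 6.43% of the 21728 genes, and this rose to 14.6% at 600 bp upstream and 22.3% at 1000 bp downstream, while it was 3.14% at 5 kb upstream and 5.96% at 5 kb downstream. The higher flank was 3.48 times the TSS value in the replicated list, 3.82 times in replicate 1 and 2.97 times in replicate 2.

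**Figure D3:**
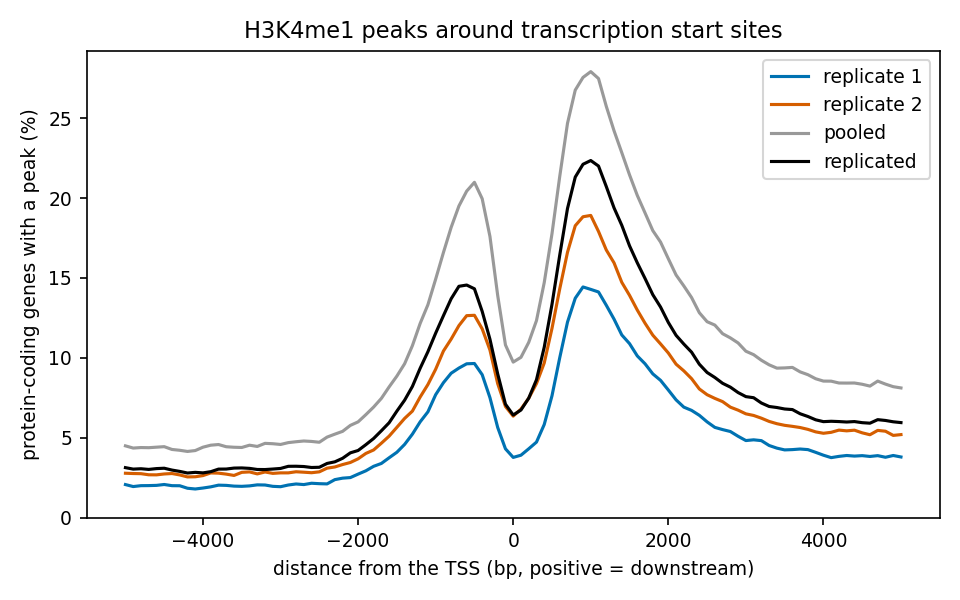
Percent of the 21728 protein-coding genes with a peak (y axis) at each distance from the TSS in bp (x axis, positive values downstream), with 1 line for each peak list. All 4 lines dip at the TSS, to 6.43% in the replicated list, and rise to a higher maximum downstream, 22.3%, than upstream, 14.6%.

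The domains with the most covered sequence lay over Msi2, Tns1 and Zmiz1. Joining neighbouring replicated peaks gave 25992 domains, of which 863 were longer than 50 kb, and these held 23.6% of the peaks. With a gap of 5 kb there were 39440 domains. The domain with the most covered sequence, on chromosome 11 (88351364 to 88716320), spanned 365 kb over Msi2, an RNA-binding protein gene, with 130 peaks over 135 kb. The next were at Tns1, which encodes a focal adhesion protein, with 118 kb covered, at Zmiz1 with 95.5 kb, and at the collagen genes Col4a1 and Col4a2 with 91.5 kb. Domains over Mical2 and Dkk3, Sorbs1, Rbpms, Nfib, Arid1b and Nfia completed the 10 largest, with 84.5 to 70.6 kb covered. Among single genes, E030018B13Rik had the highest coverage at 78.8%, but it lies inside Klf13, which had 49.5%. It was followed by Crip2 at 58.5%, Trim11 at 54.2%, the transforming growth factor regulator Ski at 53.8% and the retinoic acid receptor gene Rara at 53.1%. The order of these genes is that of the replicated list only. In replicates 1 and 2 Crip2 had 24.8% and 43.5%, below Ski (34.95% and 47.8%) and Rara (37.1% and 47.1%). Thra, a thyroid hormone receptor gene, had 46.6% and Actn4, a non-muscle actinin gene, 47.0%.

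The peak of highest signal, on the authors' scale, lay on chromosome 7 (141326029 to 141327511) within 1 kb of the TSS of Deaf1, with a signal of 8.94. Of the 10 strongest replicated peaks, others lay in introns of Nol4l (chromosome 2, 153432943 to 153438833, signal 8.64), of Lifr, the receptor for leukaemia inhibitory factor (chromosome 15, 7151709 to 7153162, signal 8.59), and of Zcchc24 (chromosome 14, 25734412 to 25736656, signal 8.50). A pair of them lay in Bcl9l, a Wnt pathway cofactor gene, in an exon (signal 8.29) and an intron (signal 7.97).

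The MEF2 binding sequence was the most enriched of 20 consensus sequences in distal peaks. Windows of 1 kb on replicated peaks over 1 kb from any TSS were compared with windows 5 kb away that met no pooled peak. The control windows were not filtered by distance from a TSS, so some can lie at promoters. The MEF2 consensus CTAWWWWTAG, bound by the myocyte enhancer factors, occurred at 0.0524 per kb in peaks and 0.0151 per kb in control windows, a ratio of 3.47, while the median ratio of 50 letter permutations of the same consensus was 0.868. The replicates' own peaks gave 3.01 ± 0.106 (SD, n = 2). The consensuses for ERG (ratio 1.35), the muscle E-box (1.38), TEAD (1.21), AP-1 (1.21) and GATA (1.16) also exceeded all of their permutations (29 for GATA and 50 for the others). The estrogen-related receptor consensus had a ratio of 1.49, at the 96th percentile of its permutations, and reached at least the 98th under 5 alternatives, 1 of them chosen after seeing the data. RUNX stood at the 98th percentile with a ratio of 0.971, below 1, and fell inside the central 95% with 400 bp windows, with controls at 10 kb or in replicate 2 alone. The T-box consensus was less frequent in peaks than in controls (0.822), at the 6th percentile, which is inside the central 95%. Consensuses for NKX2, SRF, HAND, ETS, FOX, SOX, PU.1, KLF, CTCF and HNF1 did not stand apart at the main setting. The HAND and neuronal E-box consensuses are reverse complements and gave 1 measurement (ratio 1.01). Peak windows had 46.3% GC and control windows 44.4%.

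**Figure D4:**
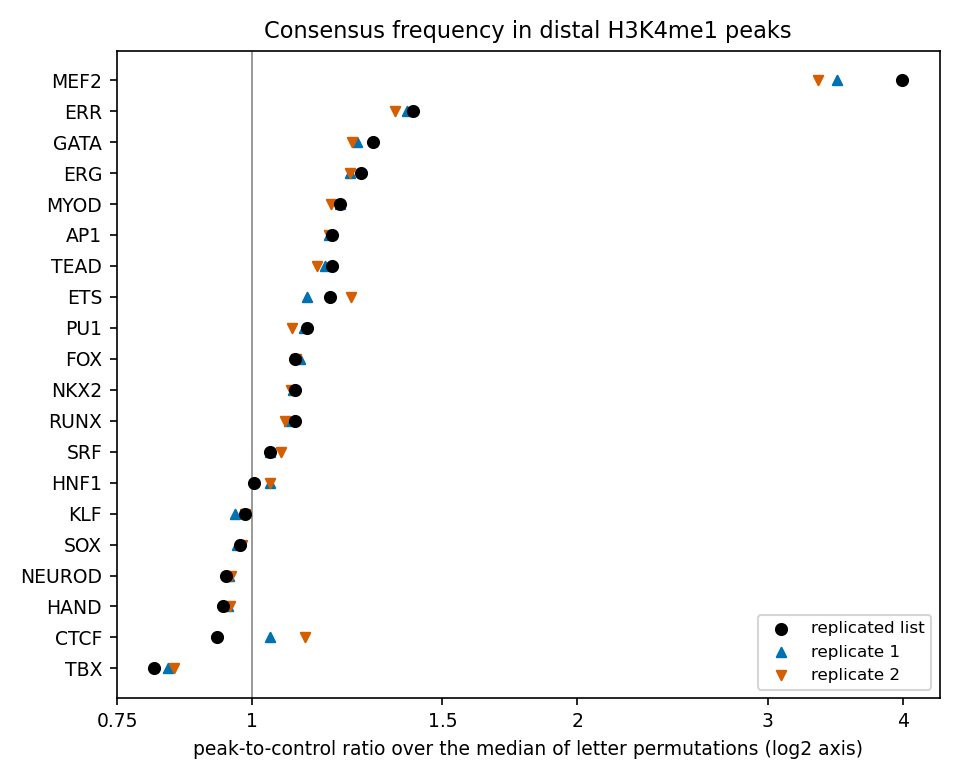
Ratio of consensus frequency in peak windows to control windows, divided by the median ratio of letter permutations (x axis, log2 scale), for 20 consensuses (y axis), with black circles for the replicated list and triangles for the 2 replicates. MEF2 lies at 4.00 in the replicated list, and the next highest, ERR, at 1.41.

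Chromosome X carried few peaks. It had 305 replicated peaks, or 1.87 per Mb, against a median of 38.6 per Mb over the 19 autosomes and a lowest autosome value of 28.9. The autosome median was 20.7 times the X value in the replicated list and 12.1 ± 0.411 times in the replicates (SD, n = 2), and in covered sequence per Mb it was 31.7 times. In the pooled list the deficit was smaller, 7.94 times, with 10.9 peaks per Mb on X against 86.7. Protein-coding genes per Mb differed by a factor of 1.38 only. The libraries came from mice of both sexes, and no peak lay on chromosome Y.

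**Figure D5:**
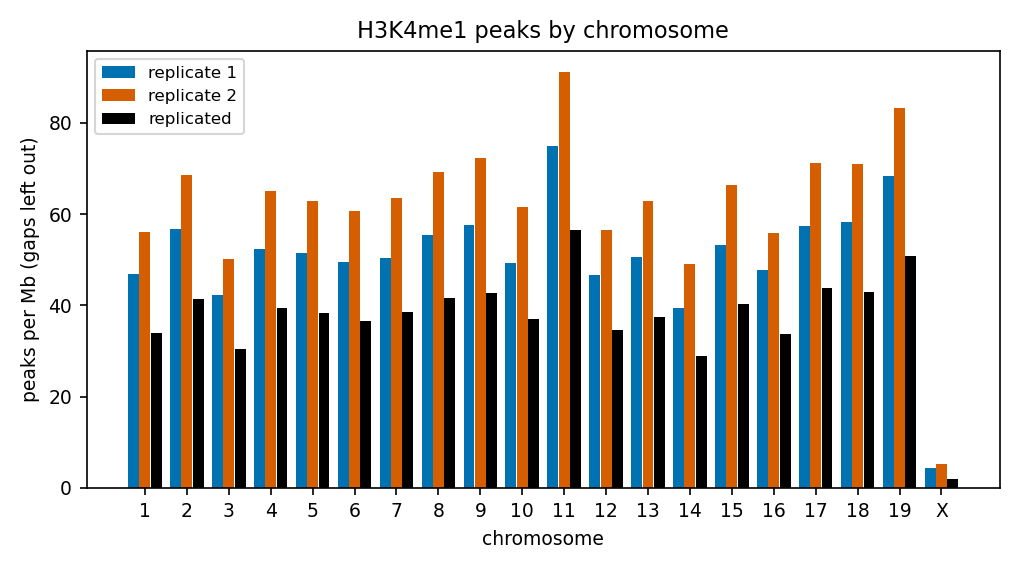
Peaks per Mb of non-gap sequence (y axis, from 0) on each chromosome (x axis) in replicate 1, replicate 2 and the replicated list (bars). Chromosome X has 1.87 replicated peaks per Mb, and the autosomes lie between 28.9 and 56.4.

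The replicates matched closely by gene and loosely by peak. Across 21728 genes the coverage of territories by the peaks of the 2 replicates had a Spearman rho of 0.912 and a Pearson r of 0.921, where genes are not independent replicates. By peak, 44.6% of replicate 1 peaks had 50% or more of their length inside replicate 2 peaks, against 2.44% ± 0.0421 after shuffling, and 30.9% of replicate 2 peaks lay in replicate 1 peaks, against 1.77% ± 0.0290 (SD, 20 shuffles). Among the strongest 10% of peaks the shares were 67.3% and 56.1%. They did not fall steadily with signal, since among the weakest 10% they were 46.3% and 27.1%. With 50% required of both peaks the shares were 24.7% and 20.1%, and with 1 bp they were 58.9% and 46.7%. The signal values of 74203 pairs of peaks that overlapped by at least 1 bp had a Spearman rho of 0.100 across peaks, and their −log10 p had 0.186. Among the strongest peaks that met no deposited peak of the other replicate were those in introns of Cdc42bpb, Adgra3 and Fyn, near the TSS of Nat8f1 and within 1 kb of a TSS for which the nearest protein-coding gene was Mex3a (its own TSS 5.76 kb away) in replicate 1, and near the TSS of Macrod1, Prelid3a, Mta1 and Pacsin1 and in an intron of Ice1 in replicate 2.

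Coverage was higher in replicate 2 in general, with a median over all protein-coding genes of 2.56%, against 1.82% in replicate 1. In some lists the difference was larger than in most random lists matched on territory length. The sarcomere median was 3.79 percentage points higher in replicate 2, at the 0.05th percentile of random lists for the difference of replicate 1 minus replicate 2. The median difference of those random lists was −0.701 points. The endothelial list (3.01 points, 0.45th percentile), the ribosomal proteins (3.41 points, 1.23rd) and the cardiac transcription factors (2.51 points, 1.45th) also lay at or below the 2.5th percentile. The call for the transcription factors ended with the same number of top peaks from each replicate (6.48th) and with all deposited peaks (14.1st). Calcium handling was at the 3.21st percentile at the main setting and at the 2.27th with all deposited peaks, but at the 53.6th with the same number of top peaks. The other 15 lists lay inside the central 95% of random lists. These compare 2 libraries and not conditions.

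The authors' replicated list was a subset of their pooled list, and it kept 44.0% of the 211702 pooled peaks. Of the strongest 10% of pooled peaks 99.2% were kept, and of the weakest 10% 10.3%. With all deposited peaks of the replicates, at any q, 47.4% of the replicated peaks had 50% or more of their length covered in both replicates and 80.7% met a peak of both by at least 1 bp. A further 5.96% were covered to 50% in neither.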

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

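The tests of gene density and of loss whatever the signal on chromosome X were chosen only after the result had been seen, and the setting without peaks beside start sites was added after seeing the data. The other tests were written down before their results.

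Strong pooled peaks lay outside the replicated list, which the main comparisons used. Of the strongest 10% of pooled peaks, 166 (0.784%) were not in the replicated list. A further signal outside the main measurement was that 38195 pooled peaks (18.0%) met no deposited peak of either replicate, at any q.

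Chromosome X had 1.87 replicated peaks per Mb against 38.6 on the median autosome, and fewer genes on X do not account for this, since X had 0.322 replicated peaks per protein-coding gene and the lowest autosome had 2.71. Repeat content is argued against as the whole cause, because a line over the autosomes gave a lower 95% prediction bound of 6.57 peaks per Mb, although X is 46.8% repeat-masked and the autosomes reach only 35.8%, so the line is extrapolated. A loss away from promoters alone is argued against by the deficit near start sites, which was 0.650 of the distal one (13.2 against 20.3 times). The first is counted per annotated start site and the second per Mb, so only the first takes out the lower gene density of X. A loss of peaks whatever their signal is argued against too, because the 90th percentile of signal on X was 3.99 and equal numbers of peaks drawn at random from the autosomes gave 4.23 to 5.03. A uniformly lower signal on X stays open, since the signal on X at ranks of 0.5, 1 and 1.5 peaks per Mb was 0.628, 0.602 and 0.565 of the autosome median, inside the range predicted for it, but random removal of autosomal peaks to the density of X also fell inside that range (0.651 to 0.756, 0.590 to 0.675 and 0.521 to 0.605, with X below all of these at rank 0.5 only), and X copy number in pooled sexes, the authors' controls and the chromatin were not tested.

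The sarcomere, endothelial, ribosomal protein and cardiac transcription factor lists were better covered in replicate 2. A higher coverage of all well covered genes in replicate 2 may account for this, because 0 of the 4 lists stayed at or below the 2.5th percentile when random lists were matched on the mean coverage of the replicates. The percentiles were 31.4 for sarcomere, 4.92 for endothelium, 7.59 for ribosomal proteins and 56.4 for transcription factors. The differences were −3.79, −3.01, −3.41 and −2.51 points, and the matched random medians were −3.18, −1.35, −2.04 and −2.70, and all 4 lists lay inside the central 95% of the matched lists and no remainder beyond their spread was shown. Depth is unknown, and the design gives no biological difference between the replicates to test.

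The ribosomal protein list and 4 heart lists stood apart. Peaks beside transcription start sites may account for the ribosomal list, which no longer stood apart without them. Its median was then 0, as was that of its random lists, so its 49.5th percentile is a tie at 0 and not a rank. Peaks beside start sites do not account for the 4 heart lists that stood apart at the main setting (transcription factors, sarcomere, calcium handling and fatty acid oxidation). Without those peaks all 4 stayed above the central 95% of random lists, with medians of 8.74%, 6.82%, 10.1% and 3.71%. No biological explanation was tested, since there was 1 group.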

How the results depend on the processing

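The 4 heart lists that stood apart at the main setting (transcription factors, sarcomere, calcium handling, fatty acid oxidation) kept their call under every alternative run. So did the MEF2, GATA, TEAD, ERG, AP-1 and muscle E-box consensuses. The natriuretic and stretch list, also of heart genes, did not stand apart at the main setting (percentile 78.6). Over all list percentiles 175 of 200 alternative values kept their call, as did 37 of 40 list differences and 111 of 120 motif percentiles. The coverage of single named genes was judged by another rule, the SD of the replicates, so its counts cannot be compared with those of the lists. Of 575 alternative values 246 stayed within that spread and 329 moved, 91 of 115 with 50 kb and 95 of 115 with replicate 1 alone. At 48 of the 115 genes the replicates differed by over 1.5 times. The cause of the changes below was not tested unless stated. Depth is unknown, so its effect was not examined. No paired analysis was possible because there was 1 group.

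Stricter thresholds lowered the number of peaks by construction, to 113553 (pooled, q 0.001), 79066 and 32884 (replicate 1, q 0.01 and 0.001) and 110224 and 59513 (replicate 2). Overlap of replicate 1 in replicate 2 was 58.9% with 1 bp and 24.7% with 50% of both peaks. In the other direction it was 46.7%, 20.1% and, at q 0.001, 21.1%. The signal correlation was 0.186 by −log10 p and 0.0755 at q 0.01 or lower in both. Peaks meeting both replicates were 80.7% with 1 bp. The share near a start site was 32.2% within 2.5 kb and 16.8% to 17.1% in single replicates. The start site dip was 2.74 at the 10455 genes with no other gene start within 10 kb and 2.97 to 3.82 in single replicates. The autosome-to-X ratio was 31.7 by covered length, 11.8 to 12.4 in single replicates and 7.94 in the pooled list. Domains numbered 39440 with a 5 kb gap.

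Cell cycle genes were at the 94.0th percentile for gene bodies, 85.6th with 50 kb, 91.2nd by the mean, 93.4th by peaks per kb, 93.8th to 95.7th in single replicates and 97.3rd with autosomal genes only. Without peaks within 2.5 kb of a start site they were at the 40.9th and ribosomal genes at the 49.5th. Both lists then had a median of 0, tied with the median of their random lists. The same setting gave 98.7 for natriuretic and stretch genes and 99.5 for endothelium. Natriuretic and stretch genes were at 99.9 with 50 kb and 98.3 by the mean. Endothelium was at 97.7 for gene bodies and 87.1 to 98.6 in single replicates. By the mean, thymus was at 2.47, hepatocytes at 1.09, pancreas and gut at 0.18 and epidermis at 0.97. With unmatched lists hepatocytes were at 2.02, pancreas and gut at 2.14 and epidermis at 2.07. With autosomal genes only, hepatocytes were at 2.02 and pancreas and gut at 1.60, and single replicates put pancreas and gut at 1.88 to 10.4.

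For the difference between replicates, cardiac transcription factors were at 6.48 with equal numbers of top peaks and 14.1 with all deposited peaks, and calcium handling was at 2.27 with all and 53.6 with equal numbers. Skeletal muscle coverage was at 25.9 to 77.0 in single replicates, and lung at 57.5 in replicate 2 and 60.7 with 50 kb. ETS was at the 90th to 100th percentile in single replicates. ERR was at 98 with 400 bp windows, with controls at 10 kb and in both single replicates, and at 100 with permutations of equal CpG. RUNX was at 94 with 400 bp windows, 88 with controls at 10 kb and 96 to 98 in single replicates.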

Other observations

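The tests of the MEF2 consensus were written down before their results, and the gene families were looked at after seeing the data. Genes of smell and pheromone detection lay almost wholly outside replicated peaks. Of 1134 olfactory receptor genes 96.5% had no replicated peak in their territory, as had 98.8% of 330 vomeronasal receptor genes, against 24.1% of the other 20264 protein-coding genes. Unlike the lists, these families were not matched on territory length. Alignments were not used, so it was not examined how well reads could be placed at these genes. Strong peaks were also wide, with a median of 1010 bp in the strongest 10% of replicated peaks and 520 bp in the weakest 10%, while the share within 1 kb of a start site was 20.2% and 19.3%.

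A hypothesis was that the MEF2 consensus rises with peak signal. The consensus occurred 1.24 times as often per kb in the strongest 10% of distal peaks as in the weakest 10%. None of 50 letter permutations reached this (highest 1.13), which was the predicted result. Windows were 1 kb for all peaks, so those on the narrower weak peaks held more flanking sequence. The permutations, with a median peak-to-control ratio of 0.868, would not show such a dilution. A rise with signal and an effect of peak width therefore cannot be told apart. A second hypothesis was that the consensus is concentrated at heart muscle genes. Its prediction of a higher share of distal peaks there was not met. The consensus was found in 2.81% of 712 distal peaks in sarcomere and calcium handling territories (Wilson 95% interval 1.83 to 4.30) and in 5.27% of 74514 distal peaks elsewhere (5.11 to 5.43), so the raw share was lower at these genes. These shares were not set against control windows or letter permutations. Base composition was thus not controlled, and the test does not decide the hypothesis. The intervals cover counting error only, and peaks of 1 gene are not independent.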
